A study of Mus musculus with 6 samples.

How the data were processed

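Kidneys of 8 week old C57BL/6J mice were dissociated with collagenase and DNase, red blood cells were lysed, and live cells carrying CD45, the surface marker of leukocytes, were sorted and put through droplet-based 3' single-cell RNA sequencing, per the labels. The 6 libraries form 2 groups, 3 from control mice and 3 from mice with acute kidney injury induced by rhabdomyolysis, the breakdown of skeletal muscle. The labels do not say that the libraries of a group come from separate animals, so the p-values measure the spread between libraries, which may be technical only.

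The deposited values are counts of unique molecular identifiers (UMIs) per gene and barcode, not normalized and not filtered for cells, in matrices that hold 32285 genes and 6 antibody tags. The submitters' processing notes name Cell Ranger and the mouse genome build mm10, and no versions were given in the sources used here. The deposited counts per library range from 10816727 to 22656666 gene UMIs. Gene names and identifiers are those of the deposited feature lists, and no coordinates were used.

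The cell filters, gene lists, marker lists, tests and alternatives described here were chosen before the data were examined, apart from the choices named as later ones. A barcode was called a cell with at least 500 UMIs, at least 200 genes, at most 15% mitochondrial UMIs, and a profile that differed from the free RNA of its library. Free RNA was profiled in barcodes with 100 or fewer UMIs and tested with a multinomial Monte Carlo test of 10000 draws, at a Benjamini-Hochberg (BH) adjusted p of at most 0.001. Doublets were scored by the share of simulated doublets among nearest neighbours within each library, and the top-scoring cells were removed, 0.8% per 1000 cells. Doublets of 2 cells of the same class are not found this way.

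Cells of all libraries were clustered together without batch correction: counts scaled to 10000 per cell and log-transformed, 2000 variable genes, 30 principal components, 20 neighbours and Leiden clustering at resolution 1. Clusters took the class with the largest share of its fixed markers over 2-fold above all other cells. Clusters with under 3 such markers, with more markers of another class among their 10 leading genes, or with low UMI counts and no own marker among those 10 stayed unnamed. These numerical thresholds, clustering only the barcodes that passed the test against free RNA, and the next rule were chosen after seeing the data. Clusters with Malat1, an abundant nuclear RNA, below 0.1% of UMIs were kept out of all classes and are called Malat1-poor.

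The share of each class was tested with the edgeR quasi-likelihood test on cell numbers, with the log of all called cells of the library as offset and BH adjustment over classes. Libraries with under 20 cells of a class were left out of that class, and a class needed 2 libraries per group. A two-sided exact permutation test of the shares stands beside it, which cannot go below 0.1 with 3 against 3 libraries. Genes were tested on UMI counts summed over the cells of a class and library with the edgeR quasi-likelihood test, trimmed mean scaling (TMM), the default expression filter and BH adjustment, and called at an adjusted p under 0.05. Standard errors (SE) of log2 changes are the change divided by the square root of its F value. The classes tested were mononuclear phagocytes (macrophage-like and monocyte-like cells joined), macrophages, classical monocytes, conventional dendritic cells, T cells, NK cells and B cells. Neutrophils and nonclassical monocytes were planned but did not have enough cells, and the comparison of macrophages with neutrophils was not possible for that reason. Differences of the change between classes were tested as an interaction with the library as a block.

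The 22 gene lists were heme and iron handling, Nrf2 and oxidative stress, inflammatory cytokines and chemokines, type I interferon response, repair and fibrosis associated macrophage genes, kidney resident macrophage genes, antigen presentation by MHC class II, lysosome and phagocytosis, complement, lipid metabolism and efflux, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, immediate early and dissociation response, endoplasmic reticulum stress, alarmins and neutrophil granule genes, leukocyte adhesion and migration, T and NK cell activation and cytotoxicity, ribosomal proteins, skeletal muscle, injured tubule and mitochondrially encoded. Lists with at least 5 tested members were tested with camera at a preset correlation of 0.01, BH over lists, with an estimated correlation and fry beside it. The 21 lists of cell type markers were tested the same way on the counts of all called cells summed per library.

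The genes named for a class were those with an adjusted p under 0.05, an average log2 CPM (UMI counts scaled to 1e6 per sample) of at least 5, all libraries of one group above all of the other, and under 20% of the counts of the higher group assigned to free RNA. Mitochondrial, ribosomal, hemoglobin, unnamed, receptor variable and sex-linked genes and the markers of the class were left out. Of these, the 10 largest rises and falls were taken for mononuclear phagocytes and macrophages and 5 of each for other classes. Not held to these bounds were up to 4 members of each gene list in its direction and 2 in the other, taken by p-value, and Hmox1, Spp1, Arg1, Il1b, Ccl2, Cd163, Lcn2, Havcr1, Mb and Ptprc in every case. The free RNA of a class and library was estimated from kidney tubule markers, on the assumption that leukocytes lack them. These markers made up 0.136% to 0.165% of free RNA in control and 0.026% to 0.030% in rhabdomyolysis libraries. Yet 1 of 6 tested markers rose in macrophages and 1 of 7 in mononuclear phagocytes, so the assumption may not hold for every marker. Where leukocytes express a marker, the free RNA estimates are too high. For a gene with 0 counts in a group the fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio of pooled rates is given with an exact 95% counting interval. Bounds and intervals cover counting error only.

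The calculations used R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. The gene test was tested on simulated data with 100 genes changed at each of 2 sizes. For a log2 change of 1 it recovered 70 genes in mononuclear phagocytes, 36 in macrophages, 17 in classical monocytes, 60 in conventional dendritic cells, 41 in T cells, 51 in NK cells and 50 in B cells. For a log2 change of 2 it recovered 93, 97, 56, 97, 80, 86 and 85 in the same order, and between 3.2% and 7.91% of all calls were unchanged genes. Cell calling recovered 93.8% to 98.4% of simulated cells per library and called at most 2 of 500 empty barcodes. The simulated cells were real cells that had passed the same test, thinned to fewer UMIs, so a high recovery was partly built in. Of simulated doublets of 2 classes, 45.3% to 72.2% were found when as many top-scoring cells were flagged as doublets were added. The filter used on the data removed a smaller share of cells, so its own recovery was not measured. Interaction tests recovered 4 of 100 genes with a log2 difference of 1 and 37 with a difference of 2 between macrophages and classical monocytes, 16 and 78 between T and NK cells, and 37 and 67 between T and B cells. Of all calls of these 3 tests 10.9%, 6% and 6.31% were unchanged genes. Libraries were checked for duplicates by a chi-square test over genes and for sex-linked genes, and none was a copy of another.

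The alternatives were DESeq2, other scalings, no expression filter, a fold threshold, free RNA subtracted, other cell filters, doublets kept, Leiden resolution 2, a replicate block, and each library left out in turn. Alternatives added after seeing the data concern Malat1-poor and unnamed clusters, clusters present in both groups and the cell minimum. The labels state no antibody tags for these libraries, and the tag counts found in the matrices were not part of the planned comparisons.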

Results

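Single-cell transcriptomes of CD45-sorted kidney cells were compared between 3 control libraries and 3 libraries from mice with rhabdomyolysis-induced acute kidney injury. The control libraries held 19427318, 17045151 and 16666253 gene UMIs and gave 3894, 3381 and 3015 called cells. The rhabdomyolysis libraries held 10816727, 15928192 and 22656666 gene UMIs and gave 1516, 2154 and 3588 called cells. Median UMIs per cell were 3337.5, 3262 and 3190 in control and 2911.5, 3349 and 2765.5 in rhabdomyolysis libraries. The median mitochondrial share was 2.48%, 2.08% and 2.23% in control and 1.26%, 1.73% and 1.51% in rhabdomyolysis libraries.

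The composition of the CD45-positive fraction differed between the groups. Classical monocyte-like cells rose from 0.736% ± 0.126 (SD, n = 3) of called cells to 14.6% ± 2.19. At Leiden resolution 2 most control monocytes were named nonclassical, as given below, so the control share includes such cells. T cell-like cells fell from 18.2% ± 1.39 to 3.59% ± 0.887, and B cell-like cells from 8.66% ± 1.90 to 3.04% ± 0.836. With Malat1-poor barcodes left out of the total, the shares were 0.891% ± 0.168 and 23.6% ± 3.71 for classical monocytes, 22.1% ± 3.10 and 5.67% ± 0.414 for T cells, and 10.4% ± 1.74 and 4.84% ± 0.779 for B cells. The log2 changes were 4.30 ± 0.35 (SE) for classical monocytes with an adjusted p of 8.87e-06, -2.35 ± 0.33 for T cells with 0.000333, and -1.51 ± 0.35 for B cells with 0.00608, in the edgeR quasi-likelihood test on cell numbers. For each of these 3 classes all 3 libraries of one group lay above all 3 of the other, and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. The sort for CD45 and recovery from it can set such shares, which are shares of sorted cells and not numbers per kidney.

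Macrophage-like cells made up 27.7% ± 3.72 of control and 20.8% ± 10.6 of rhabdomyolysis cells, a log2 change of -0.41 ± 0.44 with an adjusted p of 0.483. NK cell-like cells (log2 change -0.47 ± 0.40, adjusted p = 0.42), conventional dendritic cell 2-like cells (-0.06 ± 0.36, 0.861), innate lymphoid cell 2-like cells (0.40 ± 0.35, 0.42), endothelial-like cells (0.40, 0.581) and proliferating cells (0.90 ± 0.46, 0.133) did not pass the edgeR test. Without rhabdomyolysis replicate 3 the share of NK cells passed, with a log2 change of -0.939 and an adjusted p of 0.0071, where the other alternatives gave 0.171 to 0.982. In an alternative without a minimum of cells, chosen after seeing the data, neutrophil-like cells rose from 0.301% ± 0.00651 to 6.51% ± 2.13 (log2 change 4.41 ± 0.46, adjusted p = 1.42e-06), and kidney tubule-like cells fell from 1.5% ± 0.243 to 0.125% ± 0.0653 (-3.66 ± 0.53, 4.46e-05). In the same alternative plasmacytoid dendritic cell-like cells fell by 1.86 ± 0.67 on the log2 scale (adjusted p = 0.0299) and migratory dendritic cell-like cells by 1.83 ± 0.59 (0.0185).

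Malat1-poor clusters held 17.0% ± 5.95 of called barcodes in control and 37.1% ± 12.9 in rhabdomyolysis libraries (exact permutation p = 0.1), with 51.73% in rhabdomyolysis replicate 3. Unnamed clusters held 11.8% ± 3.67 in control and 0.821% ± 0.0256 in rhabdomyolysis libraries. Most of these were cluster 6, which resembled macrophages but had a monocyte gene among its leading genes and held 390, 500 and 220 control cells and 1 cell in each rhabdomyolysis library. The barcodes removed by the test against free RNA numbered 938, 1456 and 2256 in control and 1828, 2780 and 2777 in rhabdomyolysis libraries.

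**Figure D1:**
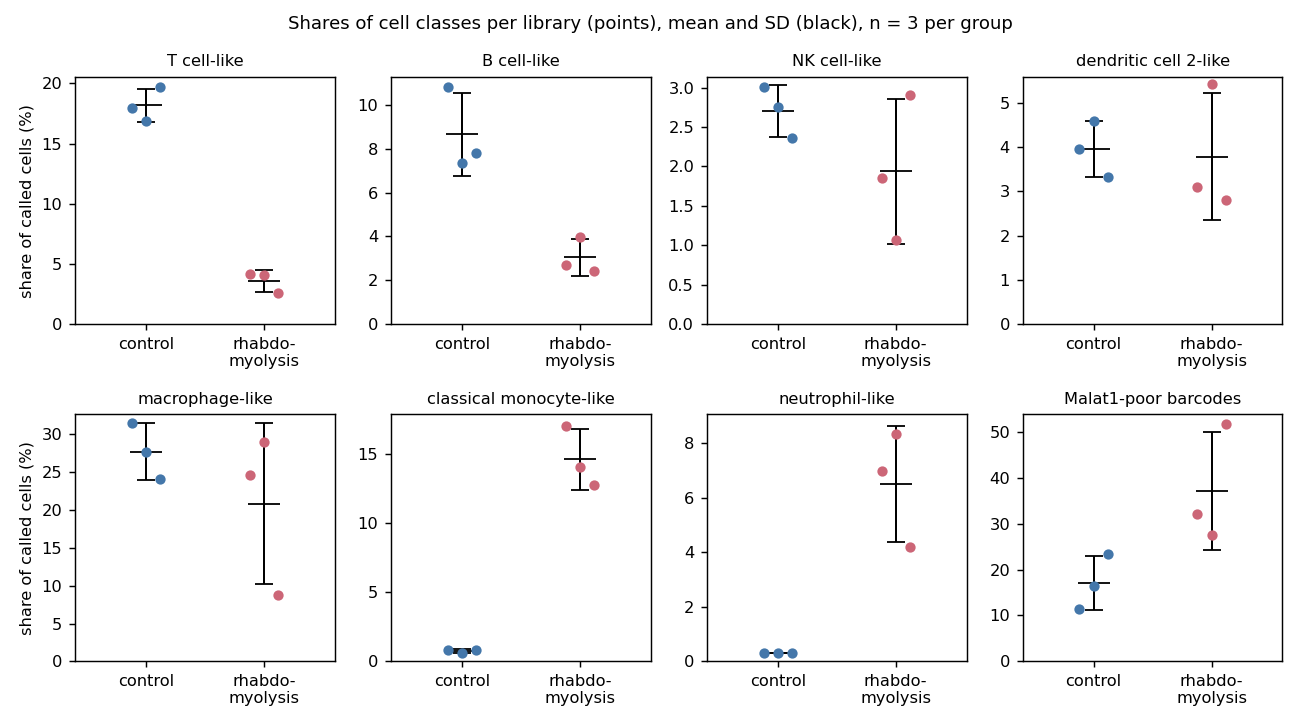
Share of called cells, in percent, of 8 cell classes in each library, with points for control (blue) and rhabdomyolysis (red) libraries and black marks for the mean and SD of 3 libraries. Classical monocyte-like cells lie at 0.736% on average in control and 14.6% in rhabdomyolysis libraries, and T cell-like cells at 18.2% and 3.59%.

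The fixed marker lists moved the same way in the counts of all called cells summed per library, which do not depend on clusters. All 9 tested neutrophil markers rose (median log2 change 4.04), as did 7 of 10 classical monocyte markers (2.04, with 1 fallen) and all 7 erythroid markers (7.35), among them hemoglobin genes. Of T cell markers 13 of 14 fell (-2.77), as did all 11 B cell markers (-2.74), all 9 plasmacytoid dendritic cell markers (-2.38), 8 of 9 conventional dendritic cell 1 markers (-1.39) and 13 of 15 kidney tubule markers (-3.60). The camera test gave adjusted p-values of 8.28e-13, 6.09e-11, 0.000634, 8.61e-20, 7.39e-14, 4.92e-05, 6.88e-06 and 1.4e-15 for these 8 lists in this order. The classical monocyte (adjusted p = 0.0368) and tubule lists (0.0402) held with an estimated correlation, and the others had adjusted p-values of 0.102 (neutrophil), 0.42 (erythroid), 0.0566 (T cell), 0.102 (B cell), 0.212 (plasmacytoid dendritic cell) and 0.212 (conventional dendritic cell 1). Lists of nonclassical monocytes (adjusted p = 0.129), macrophages (0.711), conventional dendritic cells 2 (0.166), migratory dendritic cells (0.103), plasma cells (0.103), NK cells (0.268), innate lymphoid cells 2 (0.588), proliferating cells (0.588) and endothelial cells (0.711) were not called. Mast cell or basophil, eosinophil, stromal and platelet markers had too few tested members.

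In mononuclear phagocyte-like cells, monocytes and macrophages joined, genes of MHC class II antigen presentation fell, and Spp1 and Arg1 rose. H2-Eb1 (ENSMUSG00000060586), H2-Aa (ENSMUSG00000036594) and H2-Ab1 (ENSMUSG00000073421), which encode chains of the MHC class II molecules, fell by 5.05 ± 0.14, 4.76 ± 0.13 and 4.70 ± 0.14 on the log2 scale. Ciita (ENSMUSG00000022504), the master regulator of MHC class II genes, fell by 6.01 ± 0.33. Spp1 (ENSMUSG00000029304), which encodes osteopontin, rose by 8.35 ± 0.50, and Arg1 (ENSMUSG00000019987), which encodes arginase 1, was at least 1010-fold higher, with 0 control and 3929 rhabdomyolysis counts. Of 10294 genes tested 2707 rose and 2567 fell (edgeR quasi-likelihood test, BH-adjusted p under 0.05), with adjusted p-values of 6.08e-08 for H2-Eb1, 1.69e-06 for Ciita and 2.45e-06 for Spp1. The 2 groups did not overlap for 59.9% of genes, where chance gives 10%.

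These cells were not the same mixture in both groups. Macrophage-like cells lay in cluster 1 in control (1226, 933 and 725 cells, against 0, 1 and 4) and in cluster 4 in rhabdomyolysis libraries (373, 624 and 313 cells, against 0 in each control library). Monocyte-like cells were rare in control libraries. Within mononuclear phagocytes 9 of 10 classical monocyte markers rose (median log2 change 3.65) and 10 of 14 macrophage markers fell while 3 rose (-0.92). Of 8 neutrophil markers 7 rose and 1 fell (3.96), and of 7 tubule markers 6 fell and 1 rose (-2.79). When only clusters present in both groups were kept, an alternative chosen after seeing the data that leaves cluster 13 monocytes alone, 636 genes were called. Of these, 457 were also called in the same direction in all mononuclear phagocytes and 38 in the opposite direction. In that alternative H2-Aa fell by 1.86 (adjusted p = 0.0438), H2-Eb1 (-1.9, 0.0573) and H2-Ab1 (-1.66, 0.119) were not called, and Slc7a11 and Trem1 rose by 3.72 and 3.15. Cluster 13 had 8 of 10 classical and 6 nonclassical monocyte markers over 2-fold, so its mix can differ between the groups as well.

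The other named rises in mononuclear phagocytes were Saa3, an acute phase gene, with a ratio of pooled rates of 3730 (95% counting interval 1030 to 30800), Lcn2, which encodes the iron-siderophore binding protein lipocalin 2 (3520, 632 to 139000), the neutrophil chemoattractant Cxcl3 (2140, 384 to 84600) and Lrg1 (897, 161 to 35500). AA467197 rose by 8.48 ± 0.68, Trem1, an amplifier of myeloid inflammation, by 7.82 ± 0.38, Slc7a11, the cystine transporter subunit, by 7.57 ± 0.46 and Thbs1 by 7.53 ± 0.31 on the log2 scale. The interferon-gamma inducible chemokine Cxcl9 was lower by a ratio of 841 (232 to 6950). Hspa1b, Clec4b1, Slamf7, Gpr34 and Hspa1a fell by 5.93 ± 0.90, 5.53 ± 0.28, 4.66 ± 0.22, 4.57 ± 0.30 and 4.57 ± 0.54. Arg1, Spp1, Thbs1 and Cxcl3 are among the leading genes of cluster 11, and Hspa1a and Hspa1b among those of cluster 1.

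Grouped by the fixed lists, 12 of 17 tested MHC class II genes fell and 2 rose (Cd80 and Ifi30), a median log2 change of -2.86. Of 30 kidney resident macrophage genes 20 fell and 2 rose, with Cd74 at -4.14 ± 0.14, Tmem176a at -3.36 ± 0.20 and Tmem176b at -3.09 ± 0.19. Of 20 alarmin and neutrophil granule genes 15 rose and 3 fell, with S100a6 at 5.28 ± 0.20, S100a10 at 4.96 ± 0.21 and Wfdc17 at -1.06 ± 0.15. Nrf2 and oxidative stress genes rose in 19 of 26 cases and fell in 1, with Gsr, glutathione reductase, at 3.94 ± 0.25, Prdx6 at 2.59 ± 0.16 and catalase, Cat, at -1.61 ± 0.15. Of 29 repair and fibrosis associated genes 19 rose and 6 fell, with Fn1 at 6.04 ± 0.24 and Igf1 at -3.88 ± 0.43. Of 30 inflammatory cytokine and chemokine genes 19 rose and 4 fell, with Osm at 4.49 ± 0.23 and Cxcl2 at 5.73 ± 0.36. Glycolysis and hypoxia genes rose in 16 of 23 cases with none fallen (Pkm 2.46 ± 0.14), oxidative phosphorylation genes in 37 of 42 with none fallen (Uqcrq 1.84 ± 0.17, with 31.6% of counts assigned to free RNA), and ribosomal protein genes in 26 of 43 with none fallen. Adhesion and migration genes rose in 12 and fell in 5 of 26 cases, with Vim at 3.99 ± 0.21 and Itgam at 3.01 ± 0.16. Of 10 injured tubule genes 6 rose and 2 fell, and the leading members Lcn2, S100a6, Vim and Spp1 are genes that leukocytes also express.

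The camera test called these 11 lists, with adjusted p-values of 1.51e-17 for MHC class II, 3.71e-09 for resident macrophage genes, 1.37e-20 for alarmins, 2.71e-08 for Nrf2, 2.21e-12 for repair, 4.61e-06 for inflammation, 1.49e-08 for glycolysis, 1.77e-10 for oxidative phosphorylation, 0.000325 for ribosomal proteins, 0.000451 for adhesion and 9.77e-08 for injured tubule. The MHC class II, alarmin, Nrf2 and injured tubule lists held with an estimated correlation, each with an adjusted p of 0.0316. The adjusted p with an estimated correlation was 0.162 for resident macrophage genes, 0.0762 for repair, 0.3 for inflammation, 0.204 for glycolysis, 0.332 for oxidative phosphorylation, 0.65 for ribosomal proteins and 0.425 for adhesion. Fry called all 11 and also heme and iron handling, upward (adjusted p = 0.00221). Adjusted over the list alone, 3 resident macrophage genes rose and 22 fell, 17 glycolysis, 38 oxidative phosphorylation and 28 ribosomal protein genes rose, and the counts of the other 7 lists were those over all genes. Library totals in place of TMM shifted the log2 changes of this class by -0.113.

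Lists that camera did not call in mononuclear phagocytes were heme and iron handling (9 up and 4 down of 27, adjusted p = 0.114), type I interferon response (8 and 4 of 34, 0.84), lysosome and phagocytosis (8 and 12 of 33, 0.832), complement (6 and 7 of 16, 0.406), lipid metabolism (6 and 8 of 28, 0.931), cell cycle (7 and 0 of 23, 0.114), immediate early and dissociation response (10 and 7 of 32, 0.064), endoplasmic reticulum stress (2 and 6 of 20, 0.631), T and NK cell activation (5 and 4 of 14, 0.589) and mitochondrially encoded genes (0 and 4 of 13, 0.285). Skeletal muscle genes had too few tested members in every class, and the myoglobin gene Mb had 0 counts in every class. In the heme and iron list Lrp1, a receptor for heme bound to hemopexin, rose by 2.39 ± 0.16 and Hmox1, which degrades heme, by 1.55 ± 0.20, while the iron exporter gene Slc40a1 fell by 4.17 ± 0.65 and Spic by 3.18 ± 0.25. The median and the mean differed in sign for complement (-0.10 and 0.41), lipid metabolism (-0.17 and 0.16) and immediate early genes (-0.06 and 0.24), each with an upward test direction, and the endoplasmic reticulum stress list had a positive median (0.07) and mean (0.21) and a downward test direction.

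**Figure D2:**
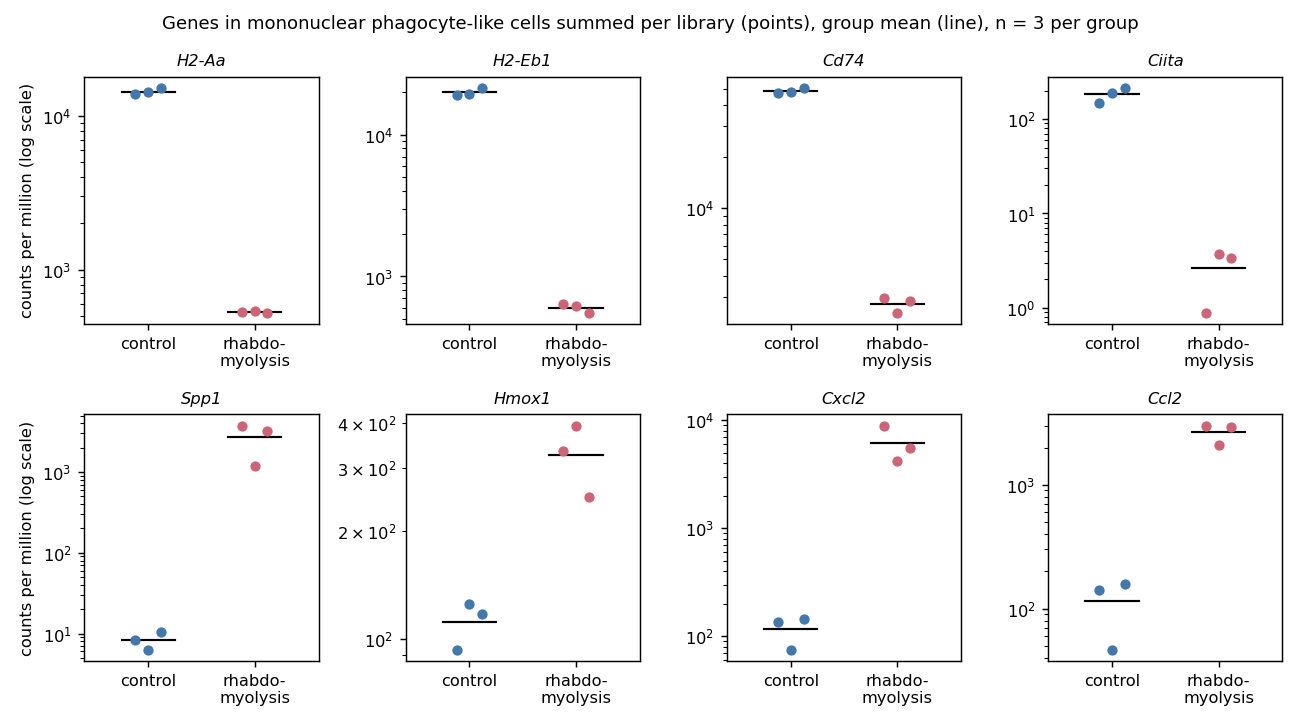
CPM, on a log scale, of 8 genes in mononuclear phagocyte-like cells summed per library, with points for control (blue) and rhabdomyolysis (red) libraries and lines for the mean of 3 libraries. H2-Eb1 lies at 19908 on average in control and 602 in rhabdomyolysis libraries.

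In macrophage-like cells alone the same MHC class II genes fell, now without the clusters named monocyte in the sum. H2-Eb1, H2-Aa and H2-Ab1 fell by 4.47 ± 0.16, 4.21 ± 0.16 and 4.15 ± 0.14 on the log2 scale, and Ciita by 5.65 ± 0.42. The neutrophil chemoattractant genes Cxcl2 and Cxcl1 rose by 5.80 ± 0.52 and 5.46 ± 0.93, Slc7a11 by 7.53 ± 0.80 and the metallothionein gene Mt2 by 7.81 ± 1.07. Mt2 lay at 459 ± 552 CPM (SD) in rhabdomyolysis libraries, with 1092 in replicate 2, and its log2 change was 6.12 without that library. That of Cxcl1 was 8.6 without control replicate 1. Of 9725 genes tested 1653 rose and 1510 fell (edgeR), H2-Eb1 with an adjusted p of 2.61e-06. The groups did not overlap for 48.3% of genes, where chance gives 10%. The count of 3163 was 1582, 1391 and 1840 without control replicates 1, 2 and 3, and 2013 and 4996 without rhabdomyolysis replicates 1 and 2. These values compare cluster 1 of the control libraries with cluster 4 of the rhabdomyolysis libraries. Cluster 4 had 6 of 14 macrophage markers over 2-fold and 0 among its 10 leading genes, where cluster 1 had 11 and 3. At Leiden resolution 2 a cluster led by Mt2, Mt1 and Jaml, with 61, 598 and 4 rhabdomyolysis cells, stayed unnamed.

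Trem1 was at least 453-fold higher in rhabdomyolysis macrophages, and Cxcl3 was higher by a ratio of 1420 (255 to 56300). AA467197, Adam8, Jaml and Nfil3 rose by 8.88 ± 0.82, 7.39 ± 0.39, 6.90 ± 1.5 and 5.68 ± 0.90. Jaml lay at 245 ± 321 CPM (SD) in rhabdomyolysis libraries, with a log2 change of 4.91 without replicate 2. Cxcl9 was lower by a ratio of 722 (129 to 28500). Hspa1b, Clec4b1, Clec12a, Slamf7 and Hspa1a fell by 5.29 ± 0.95, 5.15 ± 0.31, 4.59 ± 0.32, 4.03 ± 0.28 and 3.83 ± 0.59. Mt2 and Jaml are among the leading genes of cluster 4, and the heat shock genes Hspa1a and Hspa1b among those of cluster 1. Of 6 tubule markers 3 fell and 1 rose in this class (median -1.59). Classical monocyte markers rose in 2 and fell in 2 of 5 cases (0.67), and neutrophil markers rose in 2 and fell in 1 of 5 (2.61). Of 14 macrophage markers 5 fell and 3 rose (-0.50), 4 of 6 conventional dendritic cell 1 markers (-1.29), 3 of 6 nonclassical monocyte markers (-1.02) and both B cell markers (-2.62) fell with none risen, and both stromal markers rose (4.84). Free RNA was estimated at 15.2%, 16.6% and 12.2% of UMIs in control and 12.9%, 23.96% and 12.9% in rhabdomyolysis libraries.

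Of 17 MHC class II genes 10 fell and 1 rose in macrophages (median -2.33). Resident macrophage genes fell in 12 and rose in 4 of 30 cases, with Cd74 at -3.53 ± 0.14. Nrf2 genes rose in 15 and fell in 1 of 26 cases (Prdx6 2.22 ± 0.18, Sod2 1.48 ± 0.19), and inflammatory genes rose in 13 and fell in 3 of 27. Repair genes rose in 12 and fell in 3 of 23, with Tgfbi at 1.85 ± 0.17, F13a1, also a classical monocyte marker, at 4.40 ± 0.46 and Igf1 at -3.13 ± 0.54. Glycolysis genes rose in 13 of 21 cases, oxidative phosphorylation genes in 32 of 42, ribosomal protein genes in 20 of 43 and cell cycle genes in 7 of 18, with none fallen. Alarmins rose in 8 and fell in 3 of 12 cases, but all counts of S100a6 and S100a4 were assigned to free RNA, and Wfdc17 fell by 2.71 ± 0.17. Injured tubule genes rose in 5 and fell in 1 of 9 cases, among them Cdkn1a at 2.73 ± 0.32. The camera test called these 11 lists, with adjusted p-values from 1.29e-18 (MHC class II) to 0.00357 (alarmins and cell cycle), and with an estimated correlation the adjusted p ran from 0.0586 for MHC class II to 0.555, with 2 lists at an unadjusted p under 0.05. Fry called 9 of them, all but the inflammatory (0.0788) and cell cycle lists (0.126), and also a fall of lipid metabolism genes (0.0085). Adjusted over the list alone, 11 MHC class II genes fell and 2 rose, 17 Nrf2 genes rose, 5 repair genes fell and 35 oxidative phosphorylation genes rose. In the heme and iron list, which was not called (6 up and 3 down of 25, adjusted p = 0.617), the ferritin heavy chain gene Fth1 rose by 1.68 ± 0.20. Malat1-poor cluster 7, with Hmox1 among its leading genes, lay outside this class. The type I interferon and endoplasmic reticulum stress lists had a positive median and a negative mean and test direction, and neither was called.

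Classical monocyte-like cells of the rhabdomyolysis libraries expressed genes with 0 counts in control monocytes. Spp1 was at least 514-fold higher, Saa3 at least 113-fold, the monocyte chemoattractant gene Ccl7 at least 89.6-fold, Arg1 at least 57-fold and Cxcl3 at least 32.3-fold. In clusters present in both groups the log2 change of Spp1 was 8.93 against 15.7, both from 0 control counts. Hspa1b, Hspa1a, the prostaglandin-degrading enzyme gene Hpgd and the nonclassical monocyte marker Cd300e fell by 5.92 ± 0.66, 4.94 ± 0.54, 4.92 ± 0.27 and 4.27 ± 0.38, and Ighm, an immunoglobulin gene, by 5.03 ± 0.42. Of 7459 genes tested 736 rose and 602 fell (edgeR), which became 471 and 802 with library totals, a shift of -0.211 in log2 change. The count of 1338 was 797 without control replicate 1 and 760 and 867 without rhabdomyolysis replicates 1 and 3. The groups did not overlap for 39.3% of genes, where chance gives 10%. Control libraries gave 32, 20 and 24 such cells against 258, 303 and 457, and cluster 11, which held 0, 0 and 1 control cells, held 145, 160 and 251 of the rhabdomyolysis cells. At Leiden resolution 2 a cluster named nonclassical monocyte held 28, 15 and 21 control and 54, 67 and 121 rhabdomyolysis cells. Clusters named classical monocyte there held 4, 5 and 2 and 0, 0 and 1 control cells, and 62, 77 and 86 and 142, 162 and 251 rhabdomyolysis cells. By these counts most control monocytes were named nonclassical at that resolution, and most rhabdomyolysis monocytes classical. The groups thus differed in their mix of monocytes, and changes in this class cannot be told apart from that mix.

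All 9 nonclassical monocyte markers fell in this class (median -3.05), 9 of 14 macrophage markers rose and 2 fell (1.62), and 5 of 6 neutrophil markers rose and 1 fell, with S100a8 at least 197-fold higher. Free RNA was estimated at 6.34%, 2.86% and 4.93% of UMIs in control and 12.0%, 11.7% and 28.3% in rhabdomyolysis libraries. The control estimates rest on 13, 5 and 8 tubule marker UMIs, too few for a share per library. Inflammatory genes rose in 16 and fell in 2 of 26 cases (median 2.66, or 2.31 with genes at 0 set to their bound), with Ccl2 at 4.21 ± 0.25 and Cxcl2 at 4.95 ± 0.33. Repair genes rose in 16 and fell in 1 of 27 cases (2.60, or 2.52 at the bound), with the cathepsin genes Ctsl at 4.48 ± 0.34 and Ctsd at 2.52 ± 0.19. Nrf2 genes rose in 12 and fell in 1 of 25 cases (0.77, or 0.623 at the bound), complement genes rose in 7 and fell in 1 of 14 (C5ar1 4.36 ± 0.37, with 71.0%, 61.5% and 62.7% of the counts of C1qa, C1qb and C1qc assigned to free RNA), and injured tubule genes rose in 5 of 6. These 5 lists held with an estimated correlation, with adjusted p-values of 0.0184, 0.0089, 0.032, 0.0184 and 0.0089. With free RNA subtracted the list call for complement in classical monocytes remained (0.000429), while C1qc in classical monocytes was not called (0.155).

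Another 10 lists were called with the preset correlation and not with an estimated one. Fry called 8 of them, all but the immediate early (adjusted p = 0.0584) and mitochondrially encoded lists (0.184), and the 5 lists above. They rose for heme and iron handling (7 up and 3 down of 21, adjusted p = 0.0724 with an estimated correlation), lysosome (9 and 2 of 32, 0.0724), resident macrophage genes (12 and 4 of 25, 0.183), glycolysis (10 and 1 of 23, 0.179), oxidative phosphorylation (16 and 0 of 42, 0.166), alarmins (13 and 5 of 19, 0.0555) and ribosomal proteins (12 and 0 of 43, 0.314). They fell for lipid metabolism (3 up and 5 down of 26, adjusted p = 0.0798 with an estimated correlation), immediate early genes (2 and 9 of 31, 0.23) and mitochondrially encoded genes (0 and 2 of 13, 0.54). Fabp4 and the fatty acid receptor gene Cd36 fell by 4.03 ± 0.29 and 2.74 ± 0.46, and Klf4 by 2.09 ± 0.20. MHC class II genes split into 5 up and 5 down of 12 (adjusted p = 0.951), with a median of -0.77, a mean of 0.24 and an upward test direction. Adjusted over the list alone, 22 inflammatory, 20 repair and 14 Nrf2 genes rose and 15 immediate early genes fell.

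In conventional dendritic cell-like cells Il1b, Timp1 and Mmp14 rose and Cxcl9 fell. Il1b, which encodes interleukin 1 beta, rose by 3.46 ± 0.27, the tissue inhibitor gene Timp1 was at least 116-fold higher, and the metalloproteinase gene Mmp14 rose by 5.16 ± 0.36. AA467197, Fxyd7, Gpr171 and Klf9 rose by 6.44 ± 0.32, 4.24 ± 0.33, 4.03 ± 0.21 and 3.95 ± 0.58. Cxcl9 was lower by a ratio of 339 (93.6 to 2800), Upb1 at least 55.2-fold lower, and Skint3, Kctd14 and Hpgd fell by 3.75 ± 0.35, 3.72 ± 0.31 and 3.55 ± 0.19. Of 7426 genes tested 823 rose and 749 fell (edgeR), and the groups did not overlap for 37.7% of genes, where chance gives 10%. The count of 1572 was 972 and 961 without control replicates 1 and 2, and 905 with free RNA subtracted, 848 of them called in the same direction in both. The class joins 2 kinds of dendritic cells, and 8 of 9 conventional dendritic cell 1 markers fell (median -2.34), beside 5 of 7 tubule markers (-5.10). At Leiden resolution 2 a dendritic cell 2 cluster led by Cd209a held 149, 156 and 96 control and 5, 5 and 5 rhabdomyolysis cells. Another, led by Ccl17, held 16, 7 and 6 and 42, 112 and 96. Skint3 and Kctd14 are among the leading genes of the first, and Gpr171, but also the fallen Cxcl9, of the second. Changes in this class may thus follow that mix. Free RNA was estimated at 15.3%, 24.8% and 22.6% of UMIs in control and 17.2%, 34.3% and 37.8% in rhabdomyolysis libraries.

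Lists that rose in dendritic cells were inflammatory genes (13 up and 3 down of 23, adjusted p = 4.86e-05), type I interferon response (10 and 1 of 31, 0.00728), Nrf2 (10 and 2 of 24, 0.000903), repair (7 and 2 of 18, 0.00522), complement (4 and 1 of 11, 0.0219), glycolysis (9 and 3 of 21, 0.00634) and oxidative phosphorylation (10 and 2 of 42, 0.0114). Lists that fell were lipid metabolism (1 and 11 of 21, 0.00206), ribosomal proteins (1 and 17 of 43, 0.00522) and mitochondrially encoded genes (0 and 9 of 13, 0.000903). With an estimated correlation their adjusted p-values were 0.228 to 0.63, with 3 lists at an unadjusted p under 0.05. Fry called 7 of them, all but the inflammatory (0.0567), interferon (0.265) and complement lists (0.0512), and also rises of alarmins (0.009) and injured tubule genes (0.00527). Oas2 and Rtp4, interferon-induced genes, rose by 2.24 ± 0.47 and 1.42 ± 0.29, with 34.8% and 29.3% of their counts assigned to free RNA, and the sterol and fatty acid synthesis genes Idi1 and Scd2 fell by 1.83 ± 0.34 and 2.92 ± 0.52. MHC class II genes rose in 7 and fell in 4 of 16 cases (adjusted p = 0.469), with H2-Ab1 at 0.35 ± 0.07 and H2-Ob at -1.86 ± 0.20. Immediate early genes had a median of -0.24, a mean of -0.05 and an upward test direction, without a call. Adjusted over the list alone, 15 inflammatory and 15 interferon genes rose and 27 ribosomal protein genes fell.

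In T cell-like cells Nfkbia and Ctla4 rose and Anxa1 fell. Nfkbia, which encodes the NF-kB inhibitor alpha, rose by 2.59 ± 0.17 and the checkpoint receptor gene Ctla4 by 3.22 ± 0.30. Tnfrsf4, Igfbp4 and the glucocorticoid-induced Tsc22d3 rose by 2.69 ± 0.35, 2.64 ± 0.33 and 2.52 ± 0.22. Anxa1 and Art2b fell by 4.27 ± 0.41 and 3.64 ± 0.68, Mmp9 was at least 9.76-fold lower, and Chst2 and Tcrg-C4 were lower by ratios of 18.2 (6.18 to 88.4) and 16.9 (4.65 to 140). All 3 rhabdomyolysis counts of Chst2 lay in replicate 3 and both of Tcrg-C4 in replicate 1. Without those libraries the fitted log2 changes were -9.72 and -9.05, which rest on no rhabdomyolysis counts and give no fold. Of 7805 genes tested 482 rose and 330 fell (edgeR, adjusted p of 3.09e-09 for Nfkbia), which became 304 and 705 with library totals, a shift of -0.252 in log2 change. The count of 812 was 514, 490 and 483 without control replicates 1, 2 and 3, and with free RNA subtracted 598 of the genes kept the call and direction and 11 were called in the opposite direction. The groups did not overlap for 30.5% of genes, where chance gives 10%.

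The T cell clusters were not shared evenly. Cluster 10, led by Cxcr6 and Xcl1, held 251, 177 and 156 control cells and 2, 0 and 1 rhabdomyolysis cells. Cluster 17, with Il7r and Igfbp4 among its leading genes, held 71, 52 and 54 control and 26, 35 and 30 rhabdomyolysis cells, of 700, 572 and 593 and of 63, 87 and 92 T cells. At Leiden resolution 2 a cluster led by Tnfrsf4, Ikzf2, Ctla4, Foxp3 and Tnfrsf9 held 37, 15 and 17 control and 14, 19 and 28 rhabdomyolysis cells. The rises of Ctla4, Tnfrsf4, Tnfrsf9, Il7r and Igfbp4 may thus follow the mix of T cells. Free RNA was estimated at 8.37%, 9.27% and 7.03% of UMIs in control and at 37.0%, 25.6% and 34.1% in rhabdomyolysis T cells, and 5 of 11 macrophage markers rose in them (median 0.58). T cell markers fell in 5 of 14 cases with none risen.

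Ribosomal protein genes rose in 39 of 43 cases in T cells (median 0.68, or 0.42 with library totals). Immediate early genes rose in 12 of 26 with 2 fallen (Klf2 2.38 ± 0.15, Junb 1.40 ± 0.14). In that list Socs3, a suppressor of cytokine signalling, rose by 4.78 ± 0.19 with 28.6% of its counts assigned to free RNA, and with free RNA subtracted the rise of Socs3 in T cells was 5.06. Inflammatory genes rose in 4 of 14 cases, with Tnfaip3 at 2.06 ± 0.19 beside Nfkbia. Complement genes rose in 3 and fell in 1 of 6 cases, with all C1q counts of the rhabdomyolysis libraries assigned to free RNA. Alarmins fell in 6 of 10 cases (S100a4 -1.95 ± 0.23), endoplasmic reticulum stress genes in 6 of 18 (Calr -1.42 ± 0.19, Pdia3 -1.26 ± 0.18), and adhesion genes in 8 of 20 with 3 risen (Ccr2 -3.08 ± 0.31, Itgal -1.72 ± 0.25, S1pr1 1.71 ± 0.20). The camera test called these 7 lists, with adjusted p-values of 1.49e-31, 1.46e-15, 1.01e-07, 0.0236, 4.08e-09, 1.17e-05 and 0.0236. With an estimated correlation their adjusted p-values were 0.177, 0.109, 0.0967, 0.177, 0.147, 0.147 and 0.396, with 5 lists at an unadjusted p under 0.05, while fry called 5 of the 7, all but complement and adhesion. T and NK cell activation genes rose in 9 and fell in 9 of 31 cases (adjusted p = 0.348), with Cxcr3 at -1.83 ± 0.18 and Nkg7 at -1.18 ± 0.16. The resident macrophage, glycolysis and MHC class II lists differed in sign between median and mean or test in T cells, and none was called. Adjusted over the list alone, 41 ribosomal protein genes rose, and 8 adhesion genes fell while 5 rose.

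In NK cell-like cells Klf9, the chemokine receptor gene Cxcr4, Nfkbiz, Nfkbia and Bhlhe40 rose by 2.89 ± 0.61, 2.15 ± 0.46, 2.11 ± 0.43, 2.11 ± 0.32 and 2.04 ± 0.25. Cxcr6, a receptor of tissue-resident lymphocytes, fell by 4.14 ± 0.47, Cd3g by 3.78 ± 0.63 and S100a4 by 3.48 ± 0.31, and Itga1 and Rgs18 were lower by ratios of 25.4 (6.84 to 213) and 11.6 (3.03 to 99.1). Cd3g is a T cell marker, and of 6 tested T cell markers 2 fell and none rose in this class (median -0.89). Cluster 20, which held mostly control cells, had 4 T cell markers over 2-fold beside 6 NK cell markers, so the falls may follow the loss of that cluster. In clusters present in both groups, here cluster 18, S100a4 was not called (-0.484, adjusted p = 0.742), and Nfkbia and Bhlhe40 rose by 1.38 and 1.25. Without rhabdomyolysis replicate 3 the log2 change of Cxcr6 was -2.73 and that of Itga1 -7.39, and Rgs18 (-6.27, 0.136) and Cd3g (-3.3, 0.0652) were not called. Itga1 and Rgs18 had no rhabdomyolysis counts outside replicate 3, so -7.39 and -6.27 are fitted values that give no fold. Cxcr4 was not called without control replicate 1 (1.88, 0.0767) or 2 (1.99, 0.0924), nor was Nfkbiz (1.61, 0.074 and 2.13, 0.0526), and with replicate number as a block neither Nfkbiz (1.79, 0.0654) nor Rgs18 (-3.16, 0.0507) was. Of 3867 genes tested 99 rose and 71 fell (edgeR), which became 61 and 147 with library totals, a shift of -0.184, and the groups did not overlap for 21.8% of genes, where chance gives 10%. The count of 170 was 82, 38 and 103 without control replicates 1, 2 and 3, and 111 and 290 without rhabdomyolysis replicates 1 and 2. Control cells lay in clusters 20 (65, 57 and 38 cells) and 18 (52, 36 and 33), and rhabdomyolysis cells in cluster 18 (22, 21 and 93), with 6, 2 and 11 in cluster 20. The free RNA estimate for NK cells rests on 14, 5 and 4 tubule marker UMIs in control and 1, 3 and 2 in rhabdomyolysis libraries, too few for a share per library.

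NK cell lists that rose were ribosomal proteins (18 of 43 up, adjusted p = 9.34e-20), inflammatory genes (6 of 7, 2.24e-09, with the chemokine genes Ccl3 at 1.88 ± 0.37 and Ccl4 at 1.83 ± 0.42), immediate early genes (4 of 20, 5.23e-05) and cell cycle (1 of 8, 0.0176). Lists that fell were alarmins (2 of 7, 4.4e-06), mitochondrially encoded genes (4 of 12, 0.00192), adhesion (4 of 20 down and 1 up, 0.0334) and endoplasmic reticulum stress, with no single member called over all genes and 2 fallen when adjusted over the list alone (0.0477). With an estimated correlation their adjusted p-values were 0.137 to 0.481, with 3 lists at an unadjusted p under 0.05, and fry had 8 lists at an unadjusted p under 0.05 and called 0. T and NK cell activation genes rose in 5 and fell in 4 of 23 cases (adjusted p = 0.813), with the granzyme gene Gzmb at 1.93 ± 0.29, Cxcr3 at -2.73 ± 0.33 and Klrg1 at -1.80 ± 0.48. Gzmb is among the leading genes of cluster 18, which held most rhabdomyolysis NK cells.

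In B cell-like cells the endoplasmic reticulum chaperone genes Calr, Hsp90b1 and Pdia6 fell. Calr, which encodes calreticulin, fell by 1.997 ± 0.25, Hsp90b1 by 1.52 ± 0.30 and Pdia6 by 1.23 ± 0.27, and Sdf2l1 was lower by a ratio of 13.3 (3.62 to 111). Ppp1r21, the phosphatase gene Ptpn22, Pik3ip1, Zfp36l2 and Sesn1 rose by 3.46 ± 0.32, 3.34 ± 0.32, 2.23 ± 0.23, 2.23 ± 0.22 and 2.08 ± 0.28. Il4i1, Rilpl2, B3gnt8 and Ms4a4c fell by 2.39 ± 0.53, 2.34 ± 0.60, 2.10 ± 0.48 and 2.07 ± 0.29. Without rhabdomyolysis replicate 3 the log2 changes of Il4i1, Rilpl2 and B3gnt8 were -8.37, -3.84 and -4.26. All 6 rhabdomyolysis counts of Il4i1 lay in replicate 3, so -8.37 is a fitted value that gives no fold. Il4i1 and B3gnt8 were not called without rhabdomyolysis replicate 1 (-2.15, 0.0566 and -1.85, 0.0591) or 2 (-1.7, 0.0856 and -1.59, 0.101), nor was Rilpl2 (-2.11, 0.103 and -1.97, 0.137), and Il4i1 without control replicate 2 (-2.35, 0.0531) and B3gnt8 without control replicate 1 (-1.94, 0.0565) also missed the threshold. Of 4868 genes tested 107 rose and 93 fell (edgeR), which became 85 and 120 with library totals, and the groups did not overlap for 23.4% of genes, where chance gives 10%. The count of 200 was 100, 86 and 112 without control replicates 1, 2 and 3, and 99 and 356 without rhabdomyolysis replicates 2 and 3. Free RNA was estimated at 28.8% of UMIs in rhabdomyolysis replicate 1 and at 4.38% to 12.9% in the other libraries. The rhabdomyolysis estimates rest on 7, 7 and 5 tubule marker UMIs, too few for a share per library. At Leiden resolution 2 the main B cell cluster held 411, 239 and 228 control and 19, 3 and 72 rhabdomyolysis cells. An unnamed cluster led by Jchain and Igha, with 10 of 11 B cell and 6 plasma cell markers over 2-fold, held 11, 8 and 7 and 22, 83 and 15. The gene and list changes in B cells may thus follow that mix.

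Endoplasmic reticulum stress genes fell in 8 and rose in 1 of 17 cases in B cells (adjusted p = 2.67e-08), mitochondrially encoded genes fell in 4 of 12 (1.14e-05), MHC class II genes in 2 of 17 (0.000476) and alarmins in 3 of 8 (0.000942). Ribosomal protein genes rose in 6 of 43 cases (2.71e-07) and lipid metabolism genes in 2 of 9 (0.00565), with 85.89% of the counts of Apoe assigned to free RNA. With an estimated correlation their adjusted p-values were 0.39 to 0.478, with 2 lists at an unadjusted p under 0.05, while fry called none of them and only a rise of T and NK cell activation genes (0.0161). Adjusted over the list alone, 9 endoplasmic reticulum stress genes fell and 15 ribosomal protein genes rose. In 4 of 11 cases the markers of B cells themselves fell. Type I interferon, resident macrophage, lysosome, complement and other lists without a call differed in sign between median, mean or test.

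**Figure D3:**
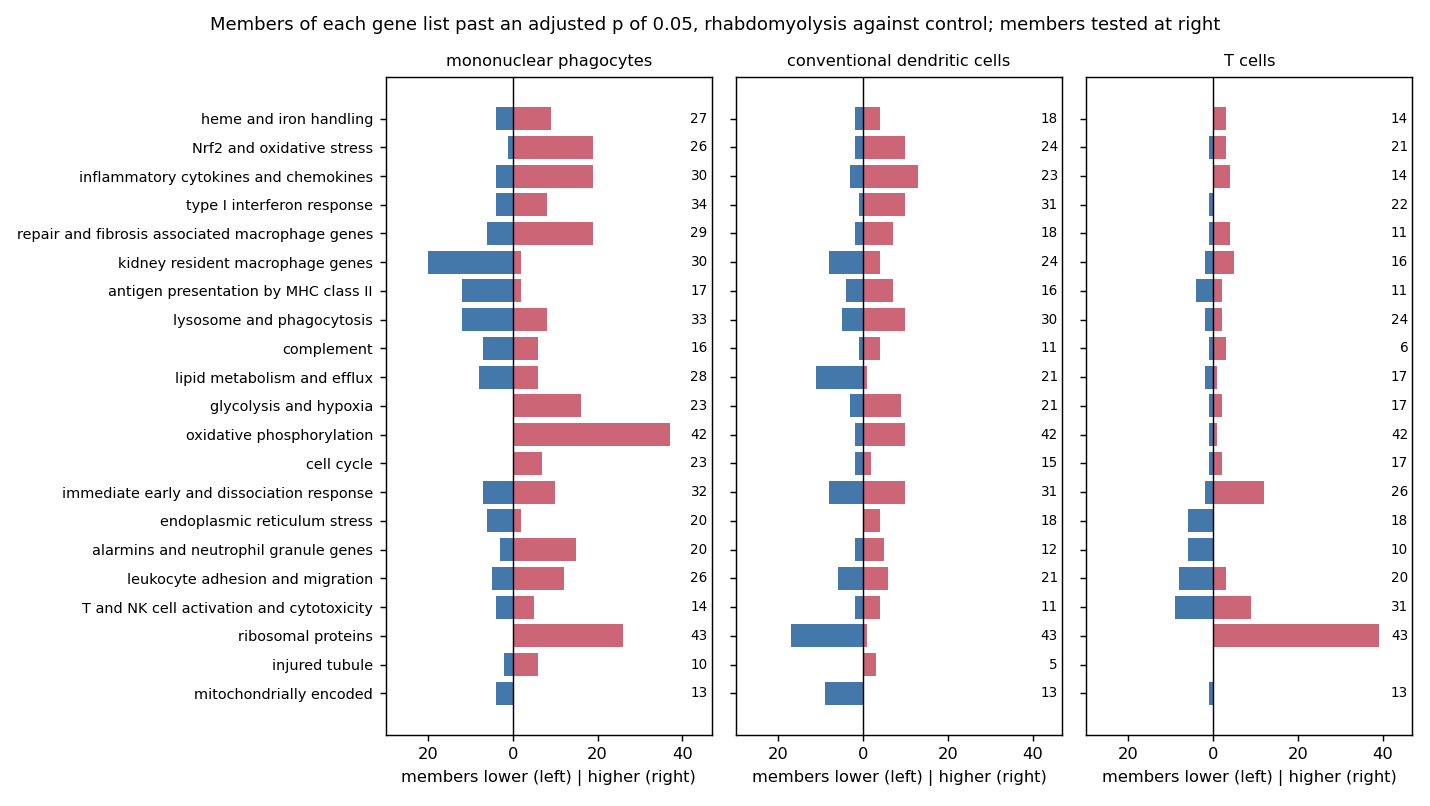
Number of members of each gene list with a BH-adjusted p under 0.05 over all genes, lower (blue, left) or higher (red, right) in rhabdomyolysis libraries, in mononuclear phagocyte-like, conventional dendritic cell-like and T cell-like cells, with the members tested at the right of each panel. MHC class II genes show 12 lower and 2 higher members of 17 in mononuclear phagocytes, and 4 lower and 7 higher of 16 in conventional dendritic cells.

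Hmox1, Il1b, Ccl2 and the other genes below were followed in every class, and their differences between classes are not read from these values. Hmox1 rose in mononuclear phagocytes (1.55 ± 0.20, adjusted p = 0.000192) and classical monocytes (1.94 ± 0.43, 0.0048) and did not pass in macrophages (0.41 ± 0.25, 0.236) or dendritic cells (0.80 ± 0.34, 0.116). It is among the leading genes of Malat1-poor cluster 7, which was kept out of all classes. That cluster had 5 macrophage and 5 erythroid markers over 2-fold. It held 188, 450 and 261 rhabdomyolysis barcodes and 1, 2 and 1 control barcodes. Il1b rose in mononuclear phagocytes (0.91 ± 0.34, 0.0471), with overlapping libraries, and in classical monocytes (2.48 ± 0.26, 4.63e-06). It did not pass in macrophages (0.93 ± 0.47, 0.157) or T cells (1.09, 0.307), and in T cells all its counts were assigned to free RNA. Ccl2, which encodes a monocyte chemoattractant, rose by 4.54 ± 0.42 in mononuclear phagocytes, 3.71 ± 0.59 in macrophages and 4.21 ± 0.25 in classical monocytes, and by 2.40 ± 0.33 in dendritic cells, where 68.5% of its counts were assigned to free RNA. Spp1 rose by 6.98 ± 0.84 in macrophages with 42.2% of counts assigned to free RNA, and by 2.61 ± 0.41 in dendritic cells with 93.3%. Arg1 was at least 24.3-fold and Lcn2 at least 70.3-fold higher in macrophages, with 86.8% and all of their counts assigned to free RNA, and Lcn2 was higher in classical monocytes by a ratio of 178 (32 to 7040). Cd163, the hemoglobin scavenger receptor, rose by 1.31 ± 0.42 in macrophages (0.0418), with overlapping libraries, fell by 3.25 ± 0.39 in dendritic cells (0.000117) and did not pass in mononuclear phagocytes (0.74, 0.266). Ptprc, which encodes CD45, fell by 1.43, 1.6, 1.67, 0.82, 0.53 and 0.78 in mononuclear phagocytes, macrophages, classical monocytes, dendritic cells, T cells and B cells, and did not pass in NK cells (-0.28, 0.454). Havcr1 had at most 4 counts in a group and class. Where one of these genes is given for a class neither here nor above, it had too few counts for the edgeR test there.

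The changes of several genes differed between classes in a direct test of the difference. Between macrophages and classical monocytes 332 of 9978 genes differed, and 26 of them were called in opposite directions. The count was 165, 176 and 162 without control replicates 1, 2 and 3 and 571 without rhabdomyolysis replicate 2. Ms4a7 fell by 2.10 in macrophages and rose by 2.12 in classical monocytes, a difference of 4.39 ± 0.35. Wfdc17 fell by 2.71 and rose by 0.97 (3.87 ± 0.26), C1qb had log2 changes of -0.03 and 3.31 (3.53 ± 0.26), and Cebpb rose by 3.47 in macrophages against 0.14 (-3.08 ± 0.25). In monocytes 61.45% of the C1qb counts were assigned to free RNA. Ms4a7 and C1qb are macrophage markers used to name clusters, and Ms4a7 is among the leading genes of cluster 1. Macrophages of the 2 groups lay in clusters 1 and 4, and the monocytes differed in their mix. The differences between these classes may thus follow which cells each class held. No macrophage cluster was present in both groups to test it. Between T and NK cells 87 of 4856 genes differed (55 without rhabdomyolysis replicate 3), 1 of them called in opposite directions. Il7r rose by 2.33 in T cells against -0.45 in NK cells (-2.54 ± 0.29) and Tnfrsf9 by 3.46 against 0.09 (-3.42 ± 0.47), while Id2 fell by 1.57 in T cells against -0.04 (1.56 ± 0.19). Il7r and Tnfrsf9 are leading genes of T cell clusters that were not shared evenly between the groups, as given above. Between T and B cells 300 of 6477 genes differed, 3 of them called in opposite directions. Klf2 rose by 2.38 in T cells against -0.09 in B cells (-2.44 ± 0.12), Bcl2 by 2.43 against 0.13 (-2.29 ± 0.22), and Ptpn22 had 0.58 in T cells against 3.34 (2.72 ± 0.28). All the differences named passed the edgeR interaction test with an adjusted p of at most 1.09e-05.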

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

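The antibody comparison, the 2 tests on Malat1-poor barcodes, and for the macrophage clusters the tests of free RNA and of dissociation were chosen after the results were seen.

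Antibody tag counts stand in the matrices although the labels state no tags for these libraries. The tag for CD4 stood at a median of 7.0 counts per classical monocyte-like cell in the middle rhabdomyolysis library, with library medians of 5.5, 7 and 9, against 2, 2 and 1.5 in control libraries. The tag for CD8a likewise stood at 7.0, with medians of 7, 7 and 10 against 3.5, 5 and 4. The control medians rest on 20 to 32 cells, and no explanation was tested.

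The change differed between macrophages and classical monocytes for 332 genes, between T and NK cells for 87 genes and between T and B cells for 300 genes, by a test of the difference itself. Each of these counts was the largest of the 10 splits of the libraries, 1 of 10, with 3, 1 and 5 genes as the highest other split. The classes held different mixes of cells in the 2 groups, as given above, and these differences may follow those mixes.

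Barcodes almost without Malat1 made up 11.43%, 16.42% and 23.28% of called barcodes in control and 32.12%, 27.53% and 51.73% in rhabdomyolysis libraries. Their F4/80 antibody median was at least 9.67 times that of B cells in each of the 6 libraries. Barcodes removed as free RNA had F4/80 medians of 54, 32, 24, 12, 20 and 25, near the 50, 29, 20, 10, 16 and 26 of these barcodes. The tag thus cannot tell pieces of macrophages without a nucleus from droplets of free RNA. Malat1-poor clusters 23, 25 and 29 had 8 of 9 conventional dendritic cell 1, 5 of 10 classical monocyte and 5 of 10 conventional dendritic cell 2 markers over 2-fold. Such separate profiles argue against a single free RNA profile per library, and against macrophages as the only source, for those clusters. For the other Malat1-poor clusters both stay open. The mitochondrial share was at most 1.18 times that of macrophage-like cells, which argues against dying cells that kept mitochondria. It also stays open whether injury or the handling of the libraries gave more of them.

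Macrophage-like cells of the 2 groups lay in different clusters, with control neighbours of rhabdomyolysis cells at 1.05% of full mixing. Of the genes called in macrophages 80.1% kept the call and direction with free RNA subtracted, which argues against free RNA as the whole cause. Rhabdomyolysis B cells had 47.7% of the control neighbours that full mixing gives, between the bounds set beforehand of 10% for a shift of whole libraries and 50% against it, with T cells at 50.5%, NK cells at 45.9% and conventional dendritic cells 2 at 13.1%. Of the called dissociation genes 60% went in the commoner direction, which decides nothing, so a dissociation response, a shift of whole libraries and the injury stay open.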

How the results depend on the processing

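The alternatives on Malat1-poor and unnamed clusters, on clusters present in both groups and without a minimum of cells were chosen after seeing the data. Over the alternatives, single-gene results kept direction and side of the threshold in 14972 cases, lost the call in 723, gained it in 271 and reversed in 5, list results kept it in 1726, lost it in 145 and gained it in 74, and shares kept it in 161 and gained it in 3 (the share of NK cells without rhabdomyolysis replicate 3, and the share of innate lymphoid cells 2 with TMM over classes and without Malat1-poor clusters in the denominator). For genes named by the rule 1714 cases kept the call and 19 lost it. These numbers hold only cases that could be tested. The named genes were picked from the same data as the largest changes without overlap, so keeping the call was largely built in. The tallies include the alternative without the test against free RNA, which kept all 90 named genes and changed gene calls in B cells only. Among all genes called in macrophages, leaving out a library kept the call and direction of 42.9% (control replicate 2) to 97.3% (rhabdomyolysis replicate 2). At Leiden resolution 2 classical monocytes and B cells had too few cells in a group, so neither their shares nor their genes were checked there. The main B cell cluster then held 19, 3 and 72 rhabdomyolysis cells, and an unnamed cluster led by Jchain and Igha held 22, 83 and 15. The cause was not tested unless stated.

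A log2 change of at least 1, a stricter rule by construction, left 2767 genes in mononuclear phagocytes, 1831 in macrophages, 871 in conventional dendritic cells, 486 in T cells and 123 in B cells. Clusters present in both groups, which means fewer cells, gave 636 genes in mononuclear phagocytes and 636 in classical monocytes, from the same cells, and 69 in NK cells. Of these, 457, 581 and 51 were also called in the same direction with all clusters, and 38 of those in mononuclear phagocytes in the opposite direction. With ambient counts subtracted 11 calls in T cells and 1 in mononuclear phagocytes changed direction among all genes tested. Leiden resolution 2 gave 5004 genes in macrophages. With ambient counts subtracted there were 905 genes in conventional dendritic cells and 85 in NK cells, and 5, 14 and 10 lists in conventional dendritic cells, T cells and B cells. DESeq2 gave 71 genes in NK cells, and without a low-count filter there were 329 genes in B cells and 500 genes differing between macrophages and classical monocytes. With replicate number as a block (replicate block) NK cells had 109 genes. Replicate numbers were not used as pairs in the main fit, since they are not said to pair libraries. The correlations of same-numbered libraries were 0.051, 0.07 and 0.119, above those of unlike numbers, which ran from -0.097 to 0.036. A pairing thus stays possible.

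With an estimated correlation camera called 4 lists in mononuclear phagocytes, 0 in macrophages, 5 in classical monocytes, and 0 in conventional dendritic cells, T cells, NK cells and B cells, with 2, 3, 5, 3 and 2 lists at an unadjusted p under 0.05 in the 5 classes at 0, and 2 marker lists. With fry there were 0 lists in NK cells, with 8 at an unadjusted p under 0.05, and 1 in B cells. Without a minimum of cells 7 classes had a changed share. Results that reversed were mt-Nd3 in mononuclear phagocytes at 10.8 with ambient counts subtracted, Wfdc17 in mononuclear phagocytes at 1.45 in clusters present in both groups, and Ctss in T cells at -8.86, Ftl1 in T cells at -12.9 and Fth1 in T cells at -14.4 with ambient counts subtracted, where subtraction brings counts to 0.

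Leaving out 1 library at a time gave 3977 to 6264 genes in mononuclear phagocytes, 1391 to 4996 in macrophages, 760 to 1043 in classical monocytes, 961 to 1830 in conventional dendritic cells, 483 to 793 in T cells, 38 to 290 in NK cells and 86 to 356 in B cells. Differences between classes ranged over 162 to 571 (macrophages and classical monocytes), 55 to 100 (T and NK cells) and 210 to 329 genes (T and B cells). Lists numbered 11 to 13, 11 to 12, 10 to 15, 10 to 13, 5 to 11, 5 to 7 and 6 to 11 in the 7 classes in that order, marker lists 8 to 11 and shares 3 to 4. The counts moved over 1.5 times in macrophages without control replicates 1, 2 and 3 (1582, 1391 and 1840) and rhabdomyolysis replicates 1 and 2 (2013 and 4996), and in classical monocytes without control replicate 1 (797) and rhabdomyolysis replicates 1 and 3 (760 and 867). They did so in conventional dendritic cells without control replicates 1 and 2 (972 and 961), and in T cells without control replicates 1, 2 and 3 (514, 490 and 483). In NK cells this held without control replicates 1, 2 and 3 (82, 38 and 103) and rhabdomyolysis replicates 1 and 2 (111 and 290), and in B cells without the control replicates (100, 86 and 112) and rhabdomyolysis replicates 2 and 3 (99 and 356). Differences between macrophages and classical monocytes moved without the control replicates (165, 176 and 162) and rhabdomyolysis replicate 2 (571), and those between T and NK cells without rhabdomyolysis replicate 3 (55). Lists moved without rhabdomyolysis replicate 3 in T cells (11) and B cells (11) and without control replicates 1 and 3 in NK cells (5 each). Leaving out a library leaves fewer samples, and summed counts limit classes with few cells. NK cells were the smallest class tested by total cells, and classical monocytes had the library with the fewest cells (20, against 23 for NK cells). The planned gene and list tests in neutrophils and nonclassical monocytes were not run under any alternative, as neither class had enough cells at resolution 1. At Leiden resolution 2 nonclassical monocytes had 28, 15 and 21 control and 54, 67 and 121 rhabdomyolysis cells, enough by the rule, but their genes were not tested there.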

Other observations

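The test of glucocorticoid targets without 2 of them was chosen after the result was seen, and so were the 3 genes that prompted it.

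Some genes changed the same way across classes that share the 6 libraries. Junb, Rbm3 and Rpl8 rose in 6 of 6 separate classes, and the genes that fell in 5 classes included Ptprc, Adgre5 and Psmb9. T and NK cells shared 72 risen genes where 8.44 would be shared if the calls were independent, and T and B cells shared 65 against 7.87. The classes come from the same libraries, so their calls are not independent, and the cause of the excess was not tested.

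Fkbp5, Tsc22d3 and Klf9, known glucocorticoid-induced genes, rose in several classes, Fkbp5 by 5.34 ± 0.50 in macrophages and 4.12 ± 0.49 in B cells, Tsc22d3 by 2.52 ± 0.22 in T cells and Klf9 by 2.89 ± 0.61 in NK cells. A candidate explanation is a glucocorticoid response, tested on 22 other targets, of which 2 (Cdc42ep3 and Cebpd) had stood in earlier output. Their median lay above 95% of matched random lists in 1 of 6 classes, T cells, at the 99.9 percentile, and again in 1 class without those 2, which argues against a response shared by the classes. NK and B cells had only 4 and 6 tested targets. With free RNA subtracted 11 of the 12 rises were kept, which argues against free RNA as their source.

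Of the 10 splits of the 6 libraries into groups of 3, the real one gave the most genes in each class, 1 of 10, which 3 against 3 libraries cannot bring below a share of 0.1. The real and highest other counts were 5274 and 0 in mononuclear phagocytes, 3163 and 0 in macrophages, 1338 and 0 in classical monocytes, 1572 and 0 in conventional dendritic cells, 812 and 0 in T cells, 170 and 0 in NK cells, 200 and 0 in B cells, and 3 and 0 for shares. For gene lists with the preset correlation 4, 3, 1, 2, 1, 1 and 2 of the 10 splits gave as many calls in these 7 classes, with real and highest other counts of 11 and 12, 11 and 11, 15 and 9, 10 and 10, 7 and 5, 8 and 5, and 6 and 8. For marker lists 7 splits gave as many, with 8 and 12. Another split thus gave as many list calls with the preset correlation in mononuclear phagocytes, macrophages, conventional dendritic cells and B cells and for marker lists, and no other split did so in classical monocytes, T cells and NK cells.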
